A study of Homo sapiens with 9 samples.

How the data were processed

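RNA was measured in A549 cells transduced with 1 of 3 lentiviral hairpins, kept for 2 days, selected with puromycin and taken after another 3 days. There were 3 groups of 3 libraries, 9 in all, prepared and sequenced by a service provider on the DNBSEQ platform. Groups and replicate numbers came from the sample titles. The values used are counts of fragments per gene that the authors deposited as 1 table for the whole series, unnormalized. Per the submitters' processing notes, FastQC, cutadapt 2.10, STAR 2.7.5a and HTSeq 0.12.4 were used with the genome build GRCh38. The strand setting of the counting and the annotation release are not given in the sources used here, so antisense genes, overlapping genes and genes with near-identical copies have uncertain counts.

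Each library held 24556848 to 24671296 fragments. Counter lines that name no gene were left out of library sizes and tests. Ambiguous fragments made up 10.8% of all fragments with shNT, 10.2% with shLITATS1-1 and 10.3% with shLITATS1-2. Fragments outside annotated features made up 2.33%, 2.49% and 2.52%, unaligned ones 3.79%, 5.56% and 5.43%, those with several alignments 2.11%, 1.88% and 1.86%, and those of low alignment quality 0.00733%, 0.00679% and 0.00775%. The gene fragments that remained numbered 19610514 to 19989652 per library. Replicates were compared in pairs by a chi-square test of counts over genes with at least 20 counts in the pair. The statistic per degree of freedom lay between 1.48 and 2.73, above sampling noise in each of the 9 pairs, so no library was taken for a second copy of another. This does not show that the libraries are independent. Whether depth or the number of replicates limits the precision more was not tested.

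Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 15500 of 60676 genes, 14614 of them with a symbol. TMM factors averaged 0.978 with shNT, 0.966 with shLITATS1-1 and 1.06 with shLITATS1-2. All 9 libraries entered 1 edgeR quasi-likelihood fit (glmQLFit, robust) with 6 residual degrees of freedom, and each pair of groups was tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are edgeR's, each with a standard error, and levels are TMM-scaled CPM unless stated otherwise. Of 40 gene lists, the 38 with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison; the immune and endothelial lists, with 4 tested genes each, were only counted. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

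The tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except those listed below as added. Named genes are LITATS1, the 12 highest and 12 lowest genes called the same way with both hairpins, ranked by the smaller of their absolute log2 fold changes, the 5 highest and 5 lowest with each hairpin and between hairpins, 18 fixed TGF-β and epithelial-mesenchymal genes, and up to 4 called members of each list; some genes that this rule names are not reported here. The rankings other than those of list members took genes with a symbol and a mean log2 CPM of at least 1. That mean was taken over all libraries, so a ranked gene can have a low level with shNT. ZC3H12A was singled out after its values were seen.

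For the overlap of both hairpins, 20 simulations drew all 9 libraries, the controls included, from the mean shNT levels, so that no group was changed. Coordinates, transcript sequences and 3′ untranslated regions were taken from GENCODE 29 on GRCh38, matched by gene identifier. Seed matches were searched with 7-mers in 11510 genes with an annotated 3′ untranslated region, 92.7% of 12415 genes at the minimum level. For each 7-mer, log2 fold changes limited to 2 in size and corrected for length and GC content of the region were compared between genes with and without it, and the z value was scaled by the spread over all 7-mers. The hairpin sequences were not used, since they are not given in the sources used here.

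The alternatives were DESeq2, DESeq2's size factors in edgeR, no filter, a filter of 50 counts, the replicate number as a block, fits of the 6 libraries compared, a threshold of 0.01, a minimum change of 2-fold, an estimated correlation for lists and the omission of each library in turn. Scaling by library size alone and corrections for GC content and gene length were added after the data were seen. The procedure was tested on simulated data for shLITATS1-1 against shNT over 15260 genes, of which 48 to 50 were changed at each size. It recovered 52.1% of genes changed 1.25-fold, 89.8% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, and 2.96% of its calls were false. Far fewer genes changed there than were called in the data. The false share therefore does not carry over to the calls below, and scaling with many changed genes was not tested by it.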

Results

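Messenger RNA and long noncoding RNA levels were measured by RNA sequencing in A549 cells, an established line of human lung adenocarcinoma with an epithelial origin. The cells carried 1 of 3 lentiviral short hairpin RNA (shRNA) constructs. The control hairpin, shNT, has no intended target, and shLITATS1-1 and shLITATS1-2 are independent hairpins against the long noncoding RNA LITATS1. Each group held 3 libraries, described in the series design as biological replicates, and nothing in the labels says whether they came from separate transductions, so p-values measure the spread between these libraries. Each library held between 24556848 and 24671296 fragments, of which 19610514 to 19989652 were assigned to genes. Of 60676 genes in the count table, 15500 had enough counts to be tested. The first principal component held 47.4% of the variance and the second 32.6%, and together they placed the 3 groups apart with the replicates of each group side by side. The common biological coefficient of variation between replicates was 2.71%, so small differences could pass the test.

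LITATS1 (ENSG00000233621) lies on chromosome 1 of GRCh38, from 37454879 to 37474411 on the minus strand, and is annotated as an antisense transcript that overlaps no other gene annotated in GENCODE 29. It was the check on the labels, with the limit that its counts depend on the strand setting and annotation release, which are not given in the sources used here. Its level was 15.1 ± 1.51 CPM (SD, n = 3) with shNT, 3.33 ± 0.405 with shLITATS1-1 and 3.02 ± 0.321 with shLITATS1-2. The remaining level was 22.0% ± 2.68 (SD, n = 3) of shNT with the first hairpin and 19.96% ± 2.12 with the second. All 6 hairpin libraries, with 56 to 72 LITATS1 fragments each, lay below the 3 shNT libraries, with 274 to 328. The log2 fold changes were -2.18 (SE 0.11) and -2.32 (SE 0.11), with adjusted p = 1.05e-27 and 3.78e-29 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same test the hairpins' LITATS1 levels differed by 0.14 (SE 0.16) on the log2 scale, which did not pass (adjusted p = 0.438).

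**Figure D1:**
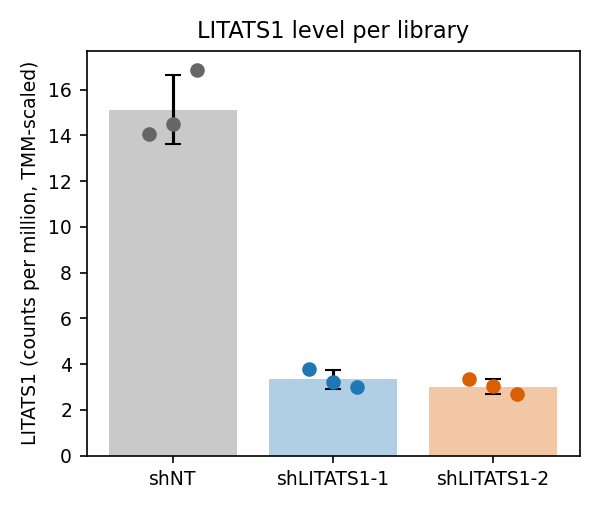
LITATS1 level in CPM for each library, by group. Bars give the mean of 3 libraries, error bars the SD and points the libraries; the means were 15.1 with shNT, 3.33 with shLITATS1-1 and 3.02 with shLITATS1-2.

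The comparison of shLITATS1-1 with shNT asks which transcripts changed when LITATS1 was depleted with the first hairpin. Genes that transforming growth factor beta (TGF-β) is known to induce rose together, as did genes of the mesenchymal state and of the extracellular matrix, while genes of DNA replication and mitosis fell. Of 52 measured TGF-β/SMAD targets, 48 rose, 3 fell and 1 did not pass, with a median log2 fold change of 1.16. TAGLN, which encodes an actin-binding protein of contractile cells, rose by 3.42, the tetraspanin gene TSPAN2 by 3.22, ITGB6, whose integrin activates latent TGF-β, by 3.00 and WNT5B, a Wnt ligand, by 2.81. TSPAN2 stood at 0.239 CPM and WNT5B at 0.684 with shNT. Among the genes fixed beforehand, the matrix protein gene TGFBI rose by 1.74 (SE 0.029), PMEPA1, a feedback inhibitor of the pathway, by 1.96 (SE 0.030) and CCN2 by 1.46 (SE 0.057). SMAD7, an inhibitory SMAD, rose by 0.82 (SE 0.056) and SKIL, a SMAD corepressor, by 0.63 (SE 0.043).

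Of 33 mesenchymal genes, 23 rose and 5 fell with shLITATS1-1. MMP9, a gelatinase, rose by 2.61, COL3A1 by 2.00 and ACTA2, smooth muscle actin, by 1.81. The cadherin gene CDH2 rose by 1.19 (SE 0.040), FN1, fibronectin, by 1.40 (SE 0.031), VIM, vimentin, by 0.26 (SE 0.030) and SNAI2, a repressor of epithelial genes, by 0.96 (SE 0.16). ZEB1 (-0.036, SE 0.053) and CDH1, encoding E-cadherin (-0.089, SE 0.055), did not pass. Of 30 epithelial genes 14 rose and 6 fell, among the former CLDN4, a tight junction claudin (2.14), CDH3 (1.67), SPINT1 (1.35) and MUC1 (1.24). CDH3 stood at 0.359 CPM with shNT. In the list of 41 matrix and basement membrane genes 34 rose and 3 fell, among them TIMP3, an inhibitor of metalloproteinases (3.11), LUM (2.95), FBN1 (2.19) and COL4A3 (2.03). Integrins and focal adhesion genes rose in 26 of 30 cases and fell in 2, with TNS1 at 2.59, ITGA5 at 1.68 and ITGB3 at 1.49. Among receptor and SMAD genes, TGFBR1 rose by 1.02 (SE 0.041), SMAD2 by 0.20 (SE 0.035) and SMURF2, a ubiquitin ligase of the pathway, by 0.30 (SE 0.045). TGFBR2 fell by 0.53 (SE 0.032) and SMAD3 fell by 0.38 (SE 0.032), and SMAD4 did not pass (0.11, SE 0.057). Of 7 measured fibroblast markers 5 rose and THY1 fell, and the list passed limma's camera test (adjusted p = 0.00521) but not with an estimated correlation (adjusted p = 0.0570 with an estimated correlation). COL1A1 rose to 41.6 ± 2.08 CPM of gene fragments (SD, n = 3) from 12.4 ± 0.629, while COL1A2, its partner chain in fibroblasts, stood at 0.0338 ± 0.0293, COL3A1 at 0.678 ± 0.251 and DCN at 0.0847 ± 0.0294. LUM rose to 3.47 ± 0.264 from 0.451 ± 0.101.

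Among 48 G1/S and replication genes, 45 fell and 2 rose with shLITATS1-1, with a median of -0.62. E2F2 changed by -1.16, CDC45 by -1.09, DSCC1 by -1.07 and the helicase subunit MCM2 by -1.01. Of 41 G2/M and mitotic genes 40 fell and none rose, with a median of -1.02, led by CENPA, the centromeric histone (-1.52), CDC20 (-1.40), KIF20A (-1.37) and the kinase PLK1 (-1.36). Of 34 p53 targets 25 rose and 3 fell. BTG2 rose by 1.61, the death receptor gene FAS by 1.46 and TIGAR by 1.40, and GDF15 fell by 1.76. Of 42 interferon-stimulated genes 33 rose and 3 fell, with GBP1 at 1.99, SAMD9 at 1.84, SAMD9L at 1.77 and OASL at 1.76. Apart from the lists, and among genes with a mean log2 CPM of at least 1, the largest increases reported here were those of LCE3D, a gene of the epidermal cornified envelope (5.97, SE 0.27), KANK4 (3.65, SE 0.28), RASGRP3 (3.58, SE 0.15) and the keratin KRT6A (3.49, SE 0.22). The mean was taken over all libraries and does not exclude low control levels. With shNT, LCE3D stood at 0.12 CPM, KANK4 at 0.27, KRT6A at 0.56 and RASGRP3 at 1.09. The largest decreases beside LITATS1 were those of LY6K (-2.67, SE 0.27), TRIM67 (-2.64, SE 0.18), CEND1 (-2.48, SE 0.15) and SEMA6B (-2.24, SE 0.066).

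In all, 9449 genes were called with shLITATS1-1 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 4728 higher and 4721 lower, and 1345 of them, 951 higher and 394 lower, had changed at least 2-fold. Correction for GC content gave 4153 higher and 5605 lower, and correction for gene length 4087 and 5612. The median absolute log2 fold change of the called genes was 0.41. Adjusted over the list alone, the counts were equal for the TGF-β/SMAD, epithelial, integrin, cell cycle, p53 and interferon lists, and were 24 higher and 5 lower for the mesenchymal, 35 and 4 for the matrix and 6 and 1 for the fibroblast list. Limma's camera test placed 26 of 38 lists apart from other genes, 16 upward and 10 downward, and 17 with an estimated correlation in place of the preset one. Mixed splits of the shNT and shLITATS1-1 libraries, which called 0 genes, still passed up to 19 lists at the preset correlation. With an estimated correlation the adjusted p was 0.00288 for TGF-β/SMAD targets, 0.00288 for the mesenchymal, 0.0327 for the epithelial, 0.00371 for the matrix and 0.00785 for the integrin list. It was 0.00417 for G1/S, 0.00391 for G2/M, 0.00538 for p53 targets and 0.00288 for interferon-stimulated genes.

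**Figure D2:**
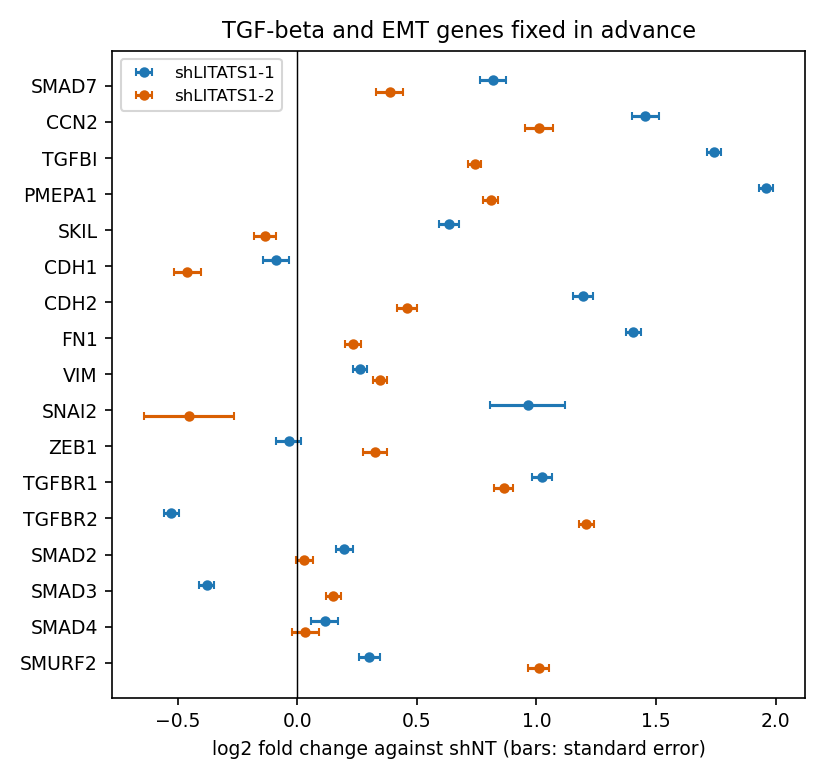
Log2 fold change against shNT (horizontal axis) of 17 of the 18 TGF-β and epithelial-mesenchymal genes fixed before the data were examined, for each LITATS1 hairpin. Points are edgeR estimates and bars their standard error; TGFBI stands at 1.74 and 0.74, and TGFBR2 on opposite sides of 0, at -0.53 and 1.21.

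The same question was asked with the second hairpin. With shLITATS1-2 the TGF-β/SMAD, mesenchymal, matrix and integrin genes also rose and the cell cycle genes also fell. Of the 52 TGF-β/SMAD targets, 41 rose, 9 fell and 2 did not pass, with a median of 0.65. MMP9 rose by 2.39, COL1A1, a fibrillar collagen, by 2.03, TAGLN by 1.97 and the gelatinase gene MMP2 by 1.92. TGFBI rose by 0.74 (SE 0.028), PMEPA1 by 0.81 (SE 0.030), CCN2 by 1.01 (SE 0.059) and SMAD7 by 0.39 (SE 0.058). SKIL fell by 0.14 (SE 0.045, adjusted p = 0.00861 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call that was lost under library-size scaling (-0.022), without shNT replicate 1 (-0.070) and without shLITATS1-2 replicate 2 (-0.094).

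Of the 33 mesenchymal genes 22 rose and 6 fell with shLITATS1-2, with TNC, the matrix protein tenascin C, at 3.09 (SE 0.091) and the fibronectin receptor subunit ITGA5 at 2.099. CDH2 rose by 0.46 (SE 0.042), FN1 by 0.23 (SE 0.032), VIM by 0.34 (SE 0.030) and ZEB1 by 0.33 (SE 0.051). CDH1 fell by 0.46 (SE 0.057). SNAI2 fell by 0.45 (SE 0.19, adjusted p = 0.0346 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call that was lost in DESeq2 (-0.45), under library-size scaling (-0.34) and without shNT replicate 3 (-0.22), shLITATS1-2 replicate 1 (-0.41) or shLITATS1-2 replicate 3 (-0.42). Epithelial genes went both ways, 11 higher and 10 lower of 30, or 15 and 8 under library-size scaling, with CLDN4 at 2.22, CDH3 at 1.23, KRT19 at 1.00 and CD24 at -0.89. Among the 41 matrix genes 28 rose and 10 fell, with TIMP3 at 2.26, NID1 at 1.36 and COL17A1 at 1.22, and 22 of 30 integrin and focal adhesion genes rose and 2 fell, with ITGB4 at 1.27 and FERMT2 at 0.92. TGFBR2, the type II receptor, rose by 1.21 (SE 0.030), SMURF2 by 1.01 (SE 0.042), TGFBR1 by 0.86 (SE 0.041) and SMAD3 by 0.15 (SE 0.031). SMAD2 (0.029, SE 0.035) and SMAD4 (0.033, SE 0.056) did not pass, but did under library-size scaling (0.14 and 0.15). COL1A1 reached 54.8 ± 1.97 CPM of gene fragments (SD, n = 3), while COL1A2 stood at 0.0340 ± 0.0294, COL3A1 at 0.594 ± 0.0298 and LUM at 0.577 ± 0.235, and of 7 measured fibroblast markers 3 rose and 1, THY1, fell.

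Replication genes fell in 44 of 48 cases with shLITATS1-2 and rose in 1, with a median of -0.55, among them UNG (-1.49), RPA2 (-1.48), RFC5 (-0.99) and MCM2 (-0.82). Mitotic genes fell in 39 of 41 cases and rose in 1, with a median of -0.52, CENPA at -0.96, MAD2L1 at -0.89, BIRC5 at -0.84 and FOXM1 at -0.82. Of 34 p53 targets 20 rose and 3 fell, with BTG2 at 1.89, BBC3, a mediator of apoptosis, at 1.26, CDKN1A, a cyclin-dependent kinase inhibitor, at 1.15 and SESN2 at 1.14. Of 42 interferon-stimulated genes 26 rose and 8 fell, with BST2 at 1.56, GBP1 at 1.35 and OAS2 at 1.13. With the same minimum level, the largest increases of single genes were those of NTSR1, a neurotensin receptor (4.45, SE 0.16), COL13A1 (3.56, SE 0.24), TNC (3.09, SE 0.091), KANK4 (2.93, SE 0.31) and SCG5 (2.69, SE 0.19). The largest decreases beside LITATS1 were those of the bicarbonate transporter gene SLC4A4 (-2.43, SE 0.13), the complement gene C5 (-2.21, SE 0.051), SPCS3, a subunit of the signal peptidase (-2.17, SE 0.050), and FBXW10 (-2.16, SE 0.23).

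In all, 8787 genes were called with shLITATS1-2 in the same edgeR test, 4302 higher and 4485 lower, and 922 of them, 586 higher and 336 lower, had changed at least 2-fold. Library-size scaling gave 6058 higher and 2967 lower, the GC correction 4102 and 4938 and the length correction 4010 and 4949. Library-size scaling moved the median of all genes by 0.11 on the log2 scale, and directions are relative to these choices. The share of gene fragments from mitochondrially encoded genes was 7.97% ± 0.235 (SD, n = 3) here, 10.2% ± 0.123 with shLITATS1-1 and 12.2% ± 0.224 with shNT. Adjusted over the list alone, the p53 list had 22 higher and 3 lower and the interferon list 27 and 8, and the other lists named for this hairpin had equal counts. Limma's camera test placed 21 of 38 lists apart, 11 upward and 10 downward, and 16 with an estimated correlation. Mixed splits of the shNT and shLITATS1-2 libraries, which called 0 genes, still passed up to 21 lists at the preset correlation. With an estimated correlation the adjusted p was 0.0109 for TGF-β/SMAD targets, 0.0113 for the mesenchymal, 0.0211 for the matrix and 0.0136 for the integrin list, 0.00926 for G1/S, 0.0224 for G2/M and 0.0136 for p53 targets. The interferon list passed camera (adjusted p = 0.0205) but not with that estimate (adjusted p = 0.0782 with an estimated correlation), the epithelial list did not pass (adjusted p = 0.576), and the fibroblast list stood at adjusted p = 0.0567.

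Genes that moved the same way with both hairpins are what a design with independent hairpins asks for. TGF-β/SMAD targets were higher with both in 40 of 52 cases, matrix genes in 27 of 41, integrin genes in 21 of 30, interferon-stimulated genes in 25 of 42, mesenchymal genes in 17 of 33 and p53 targets in 16 of 34. Replication genes were lower with both in 43 of 48 cases and mitotic genes in 39 of 41. The 12 genes highest with both were KANK4, LCE3D, PLXNA4, MAF, PCDH1, TIMP3, CHRNA9, LGR6, FST, CLDN4, SUCNR1 and PLEK2. Some of these ratios rest on low control levels. With shNT, LCE3D stood at 0.12 CPM, KANK4 at 0.27, TIMP3 at 0.43, MAF at 0.60, PLXNA4 at 0.80 and SUCNR1 at 0.97. The others of this ranking stood between 1.21 (CHRNA9) and 14.2 CPM (PLEK2). LCE3D was also low with shLITATS1-2, at 0.77 CPM. FST encodes follistatin, an antagonist of activins, and rose by 2.14 (SE 0.067) and 2.46 (SE 0.065). The axon guidance receptor PLXNA4 rose by 2.68 and 2.59, the transcription factor gene MAF by 2.40 and 2.51, PCDH1 by 2.45 and 2.30, LGR6 by 2.33 and 2.15, CHRNA9 by 2.16 and 2.35, SUCNR1 by 2.03 and 2.30, and PLEK2 by 1.99 and 2.36. The genes lowest with both, after LITATS1, were CEND1 (-2.48 and -2.104), TRIM67 (-2.64 and -1.79), HLA-DMB (-1.79 and -1.88), SPDEF (-1.94 and -1.70), ATP6V0E2-AS1 (-1.53 and -1.32), GPNMB (-1.29 and -1.86), DLEU2 (-1.95 and -1.22), POLR3G (-1.21 and -1.43), the taurine transporter gene SLC6A6 (-1.15 and -1.80), SLC51B (-1.14 and -1.34) and SLC23A1 (-1.13 and -1.63). ATP6V0E2-AS1 and DLEU2 share sequence with genes on the opposite strand, and without a stated strand setting their counts cannot be separated from those genes.

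Both hairpins called 6240 genes, 4843 in the same direction, 2362 higher and 2481 lower, and 1397 in opposite directions. Independent lists of the same sizes would share 1312 higher and 1366 lower. At least 2-fold changes were shared by 295 higher and 51 lower genes, against 36.0 and 8.54 for independent lists. Among all genes called the same way, library-size scaling gave 2770 higher and 1775 lower, the GC correction 2141 and 3100 and the length correction 2053 and 3059. Simulated unchanged groups, compared with shared simulated controls, shared 0.2 genes on average and at most 2. Part of the excess may come from the shared controls, since 3 control libraries cannot be split. The log2 fold changes correlated across genes at Pearson's r = 0.458 (Spearman's rho = 0.418), and genes are not independent replicates. Simulated unchanged groups reached 0.508 through the shared controls. That value arises from noise alone, so it cannot be ranked against the observed one. The covariance of the log2 fold changes was 0.143 against 0.0119 simulated, which leaves 0.131 as the estimate of the shared part.

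**Figure D3:**
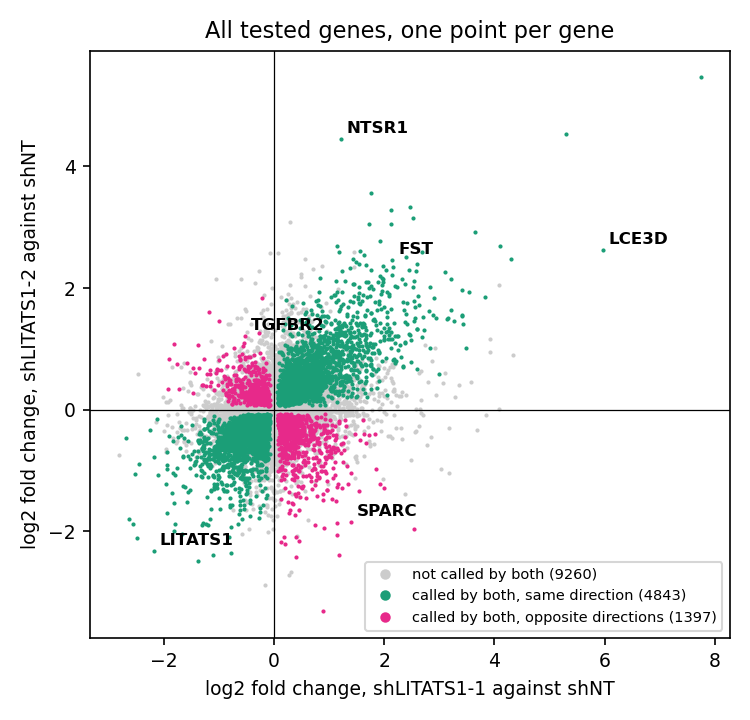
Log2 fold change against shNT with shLITATS1-1 (horizontal axis) and shLITATS1-2 (vertical axis), 1 point per gene for 15500 tested genes. Of 6240 genes called with both hairpins, 4843 lie in the quadrants of equal sign and 1397, TGFBR2 and SPARC among them, in the quadrants of opposite sign.

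The direct comparison of the hairpins asks where their effects differ. The TGF-β/SMAD response was larger with shLITATS1-1: 38 of the 52 targets were higher there and 8 were higher with shLITATS1-2. TGFBI differed by 1.00 (SE 0.028), PMEPA1 by 1.15 (SE 0.029), FN1 by 1.17 (SE 0.031) and CDH2 by 0.73 (SE 0.038) on the log2 scale. TGFBR2 was lower with shLITATS1-1 by a log2 difference of -1.74 (SE 0.031), having fallen with the first hairpin and risen with the second, and SMAD3 likewise by -0.53 (SE 0.031). Mitotic genes were lower with shLITATS1-1 in 36 of 41 cases and higher in 0. The genes furthest above, among those reported here, were LCE3D (3.34, SE 0.18), the potassium channel gene KCNJ16 (3.28, SE 0.098), SPARC, a matricellular protein (3.25, SE 0.087), and PDE3A, a phosphodiesterase (3.20, SE 0.068). SPARC stood at 34.997 ± 1.53 CPM (SD, n = 3) with shLITATS1-1, 3.68 ± 0.445 with shLITATS1-2 and 13.3 ± 0.454 with shNT. Those furthest below were NTSR1 (-3.23, SE 0.14), TNC (-2.80, SE 0.088), the aquaporin gene AQP3 (-2.73, SE 0.095), PLCH2 (-2.65, SE 0.18) and BCAN-AS2 (-2.50, SE 0.26), the last an antisense gene whose counts carry the same doubt about strand. TNC stood at 34.5 ± 0.858 CPM with shLITATS1-2 and 4.93 ± 0.592 with shLITATS1-1.

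The hairpins differed from each other in 9439 genes in edgeR's quasi-likelihood test, 4684 higher and 4755 lower with shLITATS1-1, about as many as either called against shNT, and 1289 differed at least 2-fold. Library-size scaling gave 3293 higher and 6912 lower, with the median moved by -0.13, the GC correction 4361 and 5295 and the length correction 4343 and 5268. Limma's camera test of the difference passed for 16 of 38 lists and for 2 with an estimated correlation, the TGF-β/SMAD targets (adjusted p = 0.0472 with an estimated correlation) and the interferon-stimulated genes (adjusted p = 0.0365 with an estimated correlation).

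**Figure D4:**
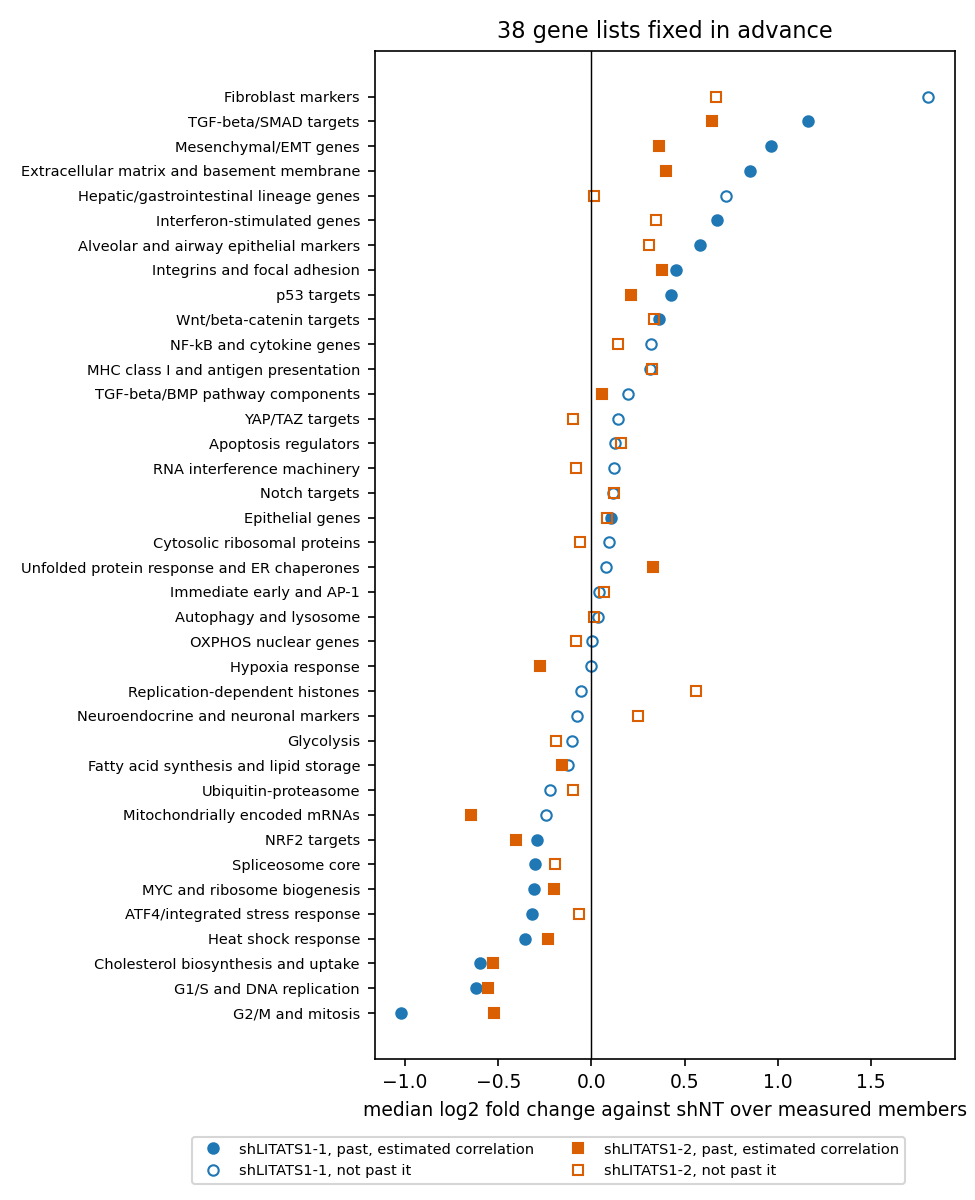
Median log2 fold change against shNT (horizontal axis) over the measured members of each of 38 gene lists, for shLITATS1-1 (circles) and shLITATS1-2 (squares). Filled symbols passed limma's camera test with an estimated correlation; TGF-β/SMAD targets lie at 1.16 and 0.65 and G2/M genes at -1.02 and -0.52.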

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

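Of the tests weighed here, the share of genes without seed matches that differ between hairpins and the medians of cell cycle genes without seed matches were set before their results were seen, and the other tests were chosen afterwards. Groups of 3 libraries are too small for a test of single outlying samples. The values below are log2 fold changes with shLITATS1-1 minus those with shLITATS1-2, each past edgeR's quasi-likelihood test of the difference with Benjamini-Hochberg adjustment. Among genes ranked by their change with both hairpins, they were 0.73 for KANK4, 3.34 for LCE3D, 0.85 for TIMP3, -0.32 for FST, -0.38 for PLEK2, -0.84 for TRIM67, 0.57 for GPNMB, -0.73 for DLEU2, 0.22 for POLR3G, 0.65 for SLC6A6 and 0.50 for SLC23A1. Among genes ranked with 1 hairpin, they were 3.13 for RASGRP3, 2.48 for KRT6A, -2.21 for LY6K, -1.91 for SEMA6B, -3.23 for NTSR1, -1.79 for COL13A1, -2.80 for TNC, -1.55 for SCG5, 2.82 for SLC4A4, 2.41 for C5, 2.30 for SPCS3 and 2.62 for FBXW10. Among genes ranked by the difference itself, they were 3.28 for KCNJ16, 3.25 for SPARC, 3.20 for PDE3A, -2.73 for AQP3, -2.65 for PLCH2 and -2.50 for BCAN-AS2. Among the fixed genes, they were 0.43 for SMAD7, 0.44 for CCN2, 1.00 for TGFBI, 1.15 for PMEPA1, 0.77 for SKIL, 0.37 for CDH1, 0.73 for CDH2, 1.17 for FN1, -0.081 for VIM, 1.42 for SNAI2, -0.36 for ZEB1, 0.16 for TGFBR1, -1.74 for TGFBR2, 0.17 for SMAD2, -0.53 for SMAD3 and -0.71 for SMURF2.

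In limma's camera test at the preset correlation, with Benjamini-Hochberg adjustment, 16 lists differed between the hairpins. With an estimated correlation 2 of them passed, TGF-β/SMAD targets (adjusted p = 0.0472) and interferon-stimulated genes (adjusted p = 0.0365), and the others had an adjusted p of at least 0.101. At the preset correlation the adjusted p was 2.84e-17 for TGF-β/SMAD targets, 0.000737 for mesenchymal, 0.0267 for epithelial and 7.66e-10 for matrix genes, 8.40e-14 for G2/M genes, 1.07e-07 for interferon-stimulated and 0.00959 for NF-kB and cytokine genes. It was 0.00669 for NRF2 targets, 0.000220 for ATF4 targets, 0.0247 for the unfolded protein response, 0.0201 for hypoxia, 5.31e-07 for mitochondrially encoded messengers, 4.83e-05 for ribosomal proteins, 0.0194 for histones, 0.0201 for alveolar and airway and 4.56e-05 for hepatic and gastrointestinal genes. Outside the gene counts, unaligned fragments made up 5.56% ± 0.0181 (SD, n = 3) with shLITATS1-1 and 5.43% ± 0.0568 with shLITATS1-2, against 3.79% ± 0.116 with shNT. Fragments outside annotated features made up 2.49% and 2.52%, against 2.33%.

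The hairpins differed from each other in about as many genes as each differed from shNT. Unequal depletion of LITATS1 is argued against, because its level did not differ detectably and 22.4% of genes called with both hairpins moved in opposite directions. Seed-dependent repression is a candidate explanation for part of it. The 7-mer with the lowest z in 3′ untranslated regions was GATTTGA with shLITATS1-1 (z = -7.49) and ACTTTCA with shLITATS1-2 (z = -14.4), both past the bound of 4.67 over 16384 7-mers. Both lie in exon 3 of LITATS1 (chromosome 1, 37455839 to 37455845 and 37455658 to 37455664), and the whole LITATS1 transcript holds 7.99% of all 7-mers. CGTGAGC also passed the bound with shLITATS1-1 (z = -4.81) and does not occur in LITATS1. The following shares cover only the 11510 genes searched for 7-mers. ACTTTCA was present in 50.6% of 178 genes at least 2-fold lower with shLITATS1-2, against 16.4% of all searched. GATTTGA was present in 19.8% of 182 genes at least 2-fold lower with shLITATS1-1, against 14.6% of all searched. ACTTTCA had 3 sites in SPCS3, 3 in SLC4A4 and 2 in PDE3A, while TGFBR2 held 2 sites of GATTTGA and C5, FBXW10 and SPARC held 0 of either. Among the genes lowest with both hairpins, TRIM67 and POLR3G held 1 site of each 7-mer and SLC6A6 held 1 of GATTTGA. CEND1, HLA-DMB, SPDEF, GPNMB, SLC51B and SLC23A1 held 0 of either. Direct matches to 11 7-mers are not the whole cause. Of 4205 genes that held none of them 65.0% still differed, against 69.3% of 7305 that held any. The 11 were GATTTGA, ACTTTCA, GAAGAGC, the 7-mer with the highest z, and the 8 past the bound that overlap GATTTGA or ACTTTCA by 6 bases. They were chosen from these same data and searched only in 3′ untranslated regions. Shorter matches and matches elsewhere in a transcript were not tested. Without the hairpin sequences the seeds remain a hypothesis.

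Both hairpins raised the TGF-β/SMAD list and lowered the cell cycle lists. Scaling as the whole cause is argued against for the fall, because 38 of 41 G2/M genes were still called lower with shLITATS1-2 under library-size scaling, which raised genes with that hairpin. For the rise it is argued against because a factor per library moves all genes alike, while the TGF-β/SMAD list differed from other genes with each hairpin (limma's camera test with an estimated correlation, the higher adjusted p = 0.0109). The 7-mer GAAGAGC had the highest z with both hairpins (5.77 and 6.89), as a seed of the shNT hairpin acting in the controls could produce. However, the 16 TGF-β/SMAD targets without a seed 7-mer of any hairpin had medians of 0.96 and 0.81. GAAGAGC occurred in 6 of 52 TGF-β/SMAD targets. Among the risen genes named above, PMEPA1, WNT5B, TGFBR1, COL4A3, FST, CLDN4, NTSR1, BTG2, BBC3, FAS and SESN2 held 1 site each. TAGLN, ITGB6, TGFBI, CCN2, SMAD7, COL1A1, MMP2 and MMP9 held 0. So did KANK4, LCE3D, PLXNA4, MAF, PCDH1, TIMP3, CHRNA9, LGR6, SUCNR1 and PLEK2. Whether these sites added to the rise of single genes was not tested. The highest of the 4 medians of cell cycle members without a seed 7-mer was -0.50, which argues against direct matches as the whole cause there. Among the replication genes named above, UNG, RPA2 and RFC5 each held 1 ACTTTCA site, and CDC45 and DSCC1 each held 1 GATTTGA site. E2F2 and MCM2 held 0 of either. Indirect effects of the shNT hairpin cannot be told apart from an effect of LITATS1 depletion, because there is no other control hairpin and the shared covariance of 0.131 holds both, and LITATS1 depletion stays open as the biological explanation.

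Other splits of the libraries were counted for each comparison. For each comparison of 3 against 3 libraries, the real split was 1 of 10, too few for a share under 0.05. The real and highest other values were 9404 and 0 genes for shLITATS1-1, 8617 and 0 for shLITATS1-2 and 9466 and 0 between the hairpins. For lists at the preset correlation they were 26 and 19 for shLITATS1-1, 22 and 21 for shLITATS1-2 and 16 and 10 between the hairpins. Mixed splits thus passed many lists while calling 0 genes, so the number of lists passed is not by itself a measure of the effect. Splits were not run with an estimated correlation. Over 100 groupings of the 9 libraries, 1 gave as many genes called the same way with both hairpins, the real one (4843, highest other 3335). The other 99 each mixed libraries of different groups and 96 of them gave 0 genes, so this excludes chance only in the sense that the libraries are not interchangeable, and does not test the agreement of the hairpins. The same groupings cannot decide whether the correlation is chance, because mixed groups of libraries that differ set r by their make-up. Of the 100, 73 gave an r as high as 0.458, the real one included, up to 0.911.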

How the results depend on the processing

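Scaling by library size alone and the corrections for GC content and gene length were chosen after the data were seen. Results for 199 named genes were compared under DESeq2, its size factors, the replicate block, library-size scaling and the omission of each library. List members named for 1 hairpin only and the other alternatives were not included. Of 5174 results, 5101 kept their side of the threshold, 66 lost the call, 7 gained one and 0 called ones changed direction. A minimum change of 2-fold left 1345 genes for shLITATS1-1, 922 for shLITATS1-2, 346 for both and 1289 between hairpins, by its construction, and an estimated correlation left 17 lists for shLITATS1-1 and 16 for shLITATS1-2, while no filter gave 28 and 28. Gene counts under the other alternatives lay between 8068 (adjusted p under 0.01) and 9758 (GC correction) for shLITATS1-1, between 7288 and 9040 for shLITATS1-2, between 3902 and 5241 for both and between 7915 (adjusted p under 0.01) and 10205 (library size) for the difference. DESeq2 kept 4082 of the 4843 genes called the same way with both hairpins, library-size scaling 3990, the GC correction 4433 and the length correction 4513. Without single libraries the counts ran from 8848 to 9612 for shLITATS1-1, 8133 to 8799 for shLITATS1-2, 4466 to 4712 for both and 8772 to 9670 for the difference, r from 0.437 to 0.485, the lists from 25 to 26 and from 20 to 24, and LITATS1 from -2.28 to -2.10 and from -2.40 to -2.24. Replicate numbers did not pair the libraries: same-numbered ones correlated at -0.061 to 0.036, others at -0.036 to 0.053, and 0 libraries correlated best with their own number in both other groups. With the replicate block, 9295, 8630, 4733 and 9264 genes were called, and 26 and 22 lists. Without shNT replicate 1 the mitochondrial list of shLITATS1-1 ended its call (adjusted p = 0.0875 in limma's camera test), and without shLITATS1-2 replicate 3 the Wnt list of shLITATS1-2 (adjusted p = 0.0515). With shLITATS1-2, fibroblast markers gained a call with the block (adjusted p = 0.0484) and without shLITATS1-1 replicate 2 (0.0486) or shLITATS1-2 replicates 1 (0.0482) or 2 (0.0419), ribosomal proteins without shLITATS1-2 replicate 1 (0.00388) or shNT replicate 1 (0.0383), the proteasome without shLITATS1-2 replicate 1 (0.0482) and YAP/TAZ targets under library-size scaling (0.0327). No filter added calls for glycolysis with both hairpins, the unfolded protein response with shLITATS1-1, and apoptosis, ATF4, ribosomal, NF-kB, oxidative phosphorylation and proteasome genes with shLITATS1-2. The cause was not tested. Depth limits the genes under the filter, which were tested only in the alternative without a filter.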

Other observations

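The tests on ZC3H12A given last were chosen after its values were seen. Counts here give called genes higher and lower with shLITATS1-1 and then with shLITATS1-2. Genes of cholesterol synthesis and uptake fell, 0 and 25 of 27, then 1 and 22, with medians of -0.60 and -0.53: IDI1 (-1.33 and -1.09) and INSIG1 (-1.10 and -0.81). IDI1 held 1 site each of GATTTGA and ACTTTCA, and INSIG1 held 2 of GATTTGA. The 12 members without a seed 7-mer had medians of -0.60 and -0.56. MYC and ribosome biogenesis genes fell, 0 and 30 of 33, then 0 and 28 (2 and 15 under library-size scaling), such as UTP20 (-0.46 and -0.69) and NPM1 (-0.34 and -0.48). NRF2 targets fell more often than they rose, 11 and 24 of 37, then 1 and 29 (5 and 24 under library-size scaling), with NR0B1 at -2.18 and -0.77, OSGIN1 at -1.64 and -0.76 and NQO1 at -0.54 and -0.85. Heat shock genes stood at 4 and 14 of 19, then 2 and 14, with HSP90AA1 at -0.71 and -1.05. These 4 lists passed limma's camera test with an estimated correlation with both hairpins (Benjamini-Hochberg adjusted p = 0.00391 and 0.00926, 0.00493 and 0.0113, 0.0344 and 0.00926, 0.0218 and 0.0136).

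Other lists passed camera with an estimated correlation with 1 hairpin. With shLITATS1-1 these were ATF4 targets (5 and 24 of 33, then 6 and 14, or 14 and 11 under library-size scaling; PHGDH of serine synthesis -1.32 and -0.77), the spliceosome (1 and 32 of 35, then 5 and 26, or 6 and 17 under library-size scaling; SF3B3 -0.39 and -0.46), Wnt targets (11 and 2 of 15, then 9 and 3; NKD1 1.30 and 1.38) and alveolar and airway markers (9 and 3 of 13, then 5 and 4, or 8 and 3 under library-size scaling; TP63 2.60 and 1.32). Their Benjamini-Hochberg adjusted p in limma's camera test was 0.0127, 0.0195, 0.0409 and 0.0409. For shLITATS1-2 the spliceosome had adjusted p = 0.0631 with an estimated correlation and the Wnt list adjusted p = 0.155 with an estimated correlation. With shLITATS1-2 they were components of the TGF-β and BMP pathway (22 and 10 of 40, then 17 and 10, or 21 and 7 under library-size scaling; BMP6 1.70 and 0.98), the unfolded protein response (14 and 4 of 26, then 19 and 4; CRELD2 0.13 and 0.94), hypoxia genes (11 and 14 of 33, then 6 and 20; MXI1 -0.48 and -1.37), lipid synthesis and storage (8 and 13 of 25, then 5 and 14; FADS1 -0.56 and -1.02) and mitochondrially encoded messengers (2 and 9 of 13, then 0 and 13; MT-ND5 -0.25 and -0.73). Their adjusted p in limma's camera test was 0.0224, 0.0128, 0.0317, 0.0211 and 0.0130. With shLITATS1-1 the pathway components had adjusted p = 0.0680 with an estimated correlation and the mitochondrial list adjusted p = 0.323 with an estimated correlation.

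Some lists passed limma's camera test at the preset correlation and not with an estimated one. With shLITATS1-1 these were YAP/TAZ targets (13 and 6 of 23, then 9 and 9, or 11 and 7 under library-size scaling; adjusted p = 0.210 with an estimated correlation), NF-kB and cytokine genes (15 and 9 of 28, then 13 and 7, or 16 and 6 under library-size scaling; adjusted p = 0.0570 with an estimated correlation), the proteasome (2 and 27 of 33, then 2 and 20, or 8 and 6 under library-size scaling; adjusted p = 0.188 with an estimated correlation), ribosomal proteins (39 and 1 of 78, then 3 and 32, or 23 and 7 under library-size scaling; adjusted p = 0.695 with an estimated correlation) and hepatic and gastrointestinal genes (13 and 2 of 16, then 4 and 5, or 5 and 5 under library-size scaling; adjusted p = 0.130 with an estimated correlation). MHC class I genes (11 and 6 of 18, then 11 and 2) had adjusted p = 0.0990 and 0.0920 with an estimated correlation, and histones with shLITATS1-2 (4 and 5 of 19, then 13 and 2) adjusted p = 0.155 with an estimated correlation. Histone and ribosomal protein genes have near-identical copies, so their counts are uncertain. The cytokine genes IL1A (1.67 and 2.38) and IL32 (1.63 and 1.24) rose, SAA1 fell (-1.24 and -1.87), and C3 (1.64 and -0.40) and CXCL5 (0.75 and -1.90) went opposite ways with the hairpins. The SAA1 call with shLITATS1-1 was lost in DESeq2 (-1.25) and without shNT replicate 1 (-1.21) or shNT replicate 3 (-1.22). It was also lost without shLITATS1-1 replicate 1 (-0.78) or shLITATS1-1 replicate 2 (-0.78). HLA-B rose by 1.34 and 1.03 and NT5E by 1.98 and 2.095.

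The remaining lists did not pass camera. They were AP-1 and immediate early genes (9 and 8 of 30, then 11 and 9, or 9 and 10, then 15 and 6 under library-size scaling), glycolysis (4 and 11 of 20, then 4 and 12), nuclear genes of oxidative phosphorylation (13 and 10 of 53, then 4 and 20, or 9 and 11, then 13 and 7 under library-size scaling), autophagy and lysosome (17 and 15 of 39, then 15 and 15, or 15 and 16, then 21 and 10 under library-size scaling), Notch targets (6 and 3 of 14, then 5 and 3), apoptosis regulators (13 and 6 of 30, then 14 and 7, or 17 and 4 under library-size scaling), RNA interference genes (6 and 5 of 13, then 5 and 5) and neuroendocrine markers (3 and 4 of 10, then 3 and 3). Of 4 measured immune markers 3 rose and 1 fell, then 1 and 1, and of 4 endothelial markers 3 and 1, then 3 and 0. JUNB rose by 1.23 and 0.93, LFNG by 1.18 and 1.44, and SQSTM1, an autophagy receptor, changed by -1.30 and -0.89. Median and mean differed in sign for YAP/TAZ targets (-0.10 and 0.17), RNA interference genes (-0.0805 and 0.0187), hepatic genes (0.011 and -0.18) and the 4 immune markers (-0.11 and 0.31) with shLITATS1-2, and for hypoxia, oxidative phosphorylation and autophagy genes with shLITATS1-1. Adjusted over the list alone, counts differed with shLITATS1-1 for NF-kB (16 and 9), oxidative phosphorylation (11 and 10), ribosomal proteins (38 and 1), autophagy (17 and 16), apoptosis (13 and 7), hepatic (14 and 2) and neuroendocrine genes (4 and 4). With shLITATS1-2 they differed for YAP/TAZ (9 and 10), AP-1 (11 and 10), heat shock (3 and 14), hypoxia (7 and 20), lipid (6 and 15), oxidative phosphorylation (4 and 19), ribosomal (2 and 30), apoptosis (14 and 8) and proteasome genes (2 and 21), and were equal for the other lists given here.

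ZC3H12A, which encodes an RNase that degrades inflammatory messengers, starts 140 bases from LITATS1 on the opposite strand (chromosome 1, 37474552 to 37484379). It rose by 0.63 (SE 0.068) and 0.63 (SE 0.067), with adjusted p = 4.12e-11 and 2.68e-11 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Shared reads are argued against by the gap of 140 bases and the opposite direction, and a rise of the whole region by 0% of 15 other tested genes within 1 Mb being higher with both hairpins, while 5 of the 15 were lower with both. Of all tested genes, 4.91% rose as much with both hairpins, so a coincidence cannot be told apart from a local effect of LITATS1 depletion, which remains a hypothesis.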
